A study of Homo sapiens with 6 samples.

How the data were processed

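Libraries were made from total RNA of SK-MES-1 cells with an mRNA library kit and sequenced on Illumina instruments, per the labels' protocols, with 3 libraries of control cells and 3 of cells given an FGF19 vector. The series design names the control cells as given a control vector. The labels give the vector type only by the letters LV. The deposited table holds, for each of 58174 genes and each library, a read count, a TPM value and an FPKM value, which scale reads to transcript length and library size. The read counts per gene are whole numbers and are not normalized, as the deposited table shows. The TPM values were made by the authors, and their sum per library lies between 999883 and 999932. The FPKM values were also made by the authors, and in each library they are the TPM values times a constant for genes above 1 FPKM, so they carry no further information. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.0, StringTie 1.3.3b and bedtools 2.26.0 were used. The program that made the counts, the annotation and the strand setting are not given in the sources used here. The submitters' processing notes name the mouse build mm9, whereas the genes of the deposited count table are human. Of the gene IDs, 57836 are in GENCODE 29, and 56001 of these have the same position there as in the table, so positions are given on GRCh38. How reads that fit several genes were treated is not given either, so genes with near-identical copies or with overlapping genes on either strand have uncertain levels.

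The 6 count columns were matched to samples by name, and 0 columns belonged to no sample of the series. There were 0 rows without a gene name, and 23803 genes had 0 counts in the 6 libraries. Totals ran from 34355593 to 42577013 counts per library, so 3 counts, the floor used for a group at 0, corresponded to 0.0705 to 0.0873 CPM of the raw total, depending on the library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

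Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with its default minimum count of 10 and minimum total of 15, which left 18729 genes, and libraries were scaled with TMM. The quasi-likelihood F test (glmQLFit and glmQLFTest) compared the groups with no covariate, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. The biological coefficient of variation was 0.208. Principal components and correlations used log2 CPM with a prior count of 2. Shares of counts were compared with two-sided exact permutation tests.

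Gene lists, 30 in number with 474 symbols, were fixed before the data were examined, as were the tests, the main alternatives and the rule for naming genes. All 474 symbols were found in the table, 5 of them by another symbol, such as CTGF for CCN2. The lists cover FGF19 receptors, MAPK feedback, glycolysis, hypoxia, the ATF4 and ER stress responses, cholesterol and fatty acid synthesis, G1/S and G2/M genes, interferon response and antigen presentation. They also cover NF-kB targets, squamous, epithelial and mesenchymal genes, matrix proteases, NRF2, p53, YAP/TAZ and FOXO targets, the BCL2 family, lysosome genes, mitochondrial and nuclear respiratory genes, ribosomal proteins and markers of leukocytes, fibroblasts and endothelium, lung and other lines. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over the 29 lists. A list's size is given as its number of tested members unless stated otherwise. For 6 lists the median, the mean and the tests did not share 1 sign. The median and the mean log2 fold change were -0.036 and 0.00081 for ATF4 genes, -0.093 and 0.10 for mesenchymal genes, -0.065 and 0.020 for p53 targets, -0.016 and 0.059 for the BCL2 family, and -0.22 and 0.076 for lung markers. Camera pointed down for p53 targets and lung markers and up for the other 3, and fry pointed down for lung markers and up for the other 4. For squamous genes the median, the mean and camera pointed up and fry down.

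The genes named are FGF19, the FGF receptors, KLB and KL, the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 5 CPM and no overlap between groups, and up to 3 members of each list with the smallest p. The 5 most abundant genes, MT-CO1, MT-ND4, MT-CO2, MT-CO3 and MT-RNR2, held 4.98%, 3.31%, 2.40%, 1.72% and 2.08% of counts in the control group and 6.12%, 3.72%, 2.49%, 2.22% and 1.73% in the FGF19 group, and 0 of the 5 were called by edgeR. Other list members and genes named in the text (VEGFA, SLC2A1, IL1B, CCL2, TNFAIP3, HERC5, OAS2, MMP14, TIMP1, TIMP3, EPCAM, SOX2, KRT17, SPRY4, SPRY1, PDK4, GCLC, ENO2, AKR1C3, CD68 and genes reported at 0 or not tested) were chosen after their values were seen.

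For a search along the chromosomes, the 11499 genes with a mean of at least 5 CPM were placed in 1068 windows of 41 neighbouring genes in steps of 10, and each window's median log2 fold change was compared with those from 100 shuffles of gene order. Alternatives covered RLE, upper-quartile and total-only scaling, FGF19 left out of the totals, no or a stricter count filter (a mean of 50), glmTreat at a log2 change of 0.5, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), the replicate number as a block, each library left out in turn, and the shifted windows left out.

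The steps were tested on simulated data, drawn for the 18729 genes from the real means, library sizes and dispersions, with 200 genes changed. Of genes changed 1.5-fold, 2-fold and 4-fold, 1.49%, 50.7% and 90.9% were called, with median estimated folds of 1.52, 2.03 and 3.95. The changed genes were drawn only from those above a minimum mean count. The adjustment is stricter when few genes change, so these shares need not hold for the real data. In that simulation 15 of 110 calls (13.6%) fell on unchanged genes, above the nominal 5%, although 4.73% of unchanged genes had an unadjusted p under 0.05. With 2000 genes changed, close to the number called in the real data, 59 of 1397 calls (4.22%) fell on unchanged genes. Of the simulated lists, the 1 list that was moved was called and no other, and a window of 41 moved genes had a median of -0.57, against at most 0.13 in size for unmoved neighbours. The simulated genes were drawn independently of each other. The simulation therefore cannot show how the list and window tests behave where genes of a list or neighbouring genes vary together.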

Results

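RNA sequencing measured the transcripts of SK-MES-1, an established human cell line of lung squamous cell carcinoma, in 3 control libraries and in 3 libraries of cells given a vector for FGF19. FGF19 is a hormone-like fibroblast growth factor that the ileum releases in response to bile acids, and it signals mainly through the receptor FGFR4 with the co-receptor KLB. The comparison asked which transcripts differ in level between cells overexpressing FGF19 and cells given a control vector. The counts assigned to genes totalled 38418982, 42011085 and 40764188 in the control libraries and 34355593, 42577013 and 38706903 in the FGF19 libraries. The labels number the samples of each group but do not say that they were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Levels are given as TMM-normalized CPM (counts scaled to library size) with the SD over 3 libraries, and log2 fold changes (FGF19 over control) with their standard error (SE). A gene was called, and is said to have risen or fallen, at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment over all genes tested).

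The libraries separated by group. The principal component of log2 CPM that held the most variance, 51.2%, placed the 3 control libraries on one side and the 3 FGF19 libraries on the other, and component 2 held 17.1%.

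**Figure D1:**
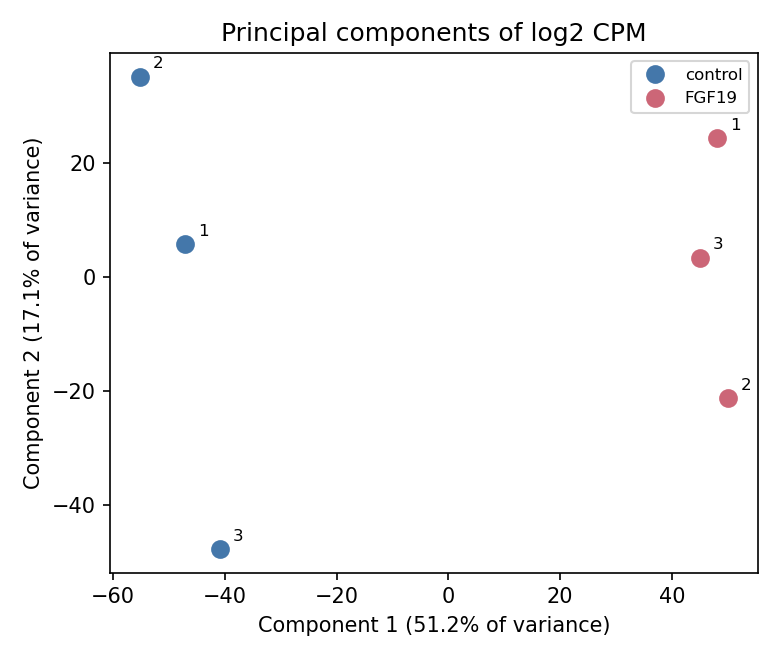
Principal components of log2 CPM over all genes tested, with component 1 (51.2% of variance) on the x axis and component 2 (17.1%) on the y axis. Each point is 1 library, coloured by group and marked with its replicate number, and the 3 control libraries lie below 0 on component 1 while the 3 FGF19 libraries lie above it.

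FGF19 itself rose from the edge of detection to a high level. The control libraries held 4, 4 and 8 counts of FGF19 and the FGF19 libraries held 56695, 80324 and 69164 counts. Its level was 0.132 ± 0.0615 CPM in the control group and 1803 ± 151 CPM in the FGF19 group (SD, n = 3), a log2 fold change of 13.72 ± 0.24 (SE, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.2e-07). FGF19 (ENSG00000162344) lies on chromosome 11 from 69698232 to 69704642 on GRCh38, and the count covers the whole gene, so transcripts of the vector and of the chromosome were not told apart. Receptor transcripts did not pass the test over all genes. FGFR1 was at 96.1 ± 5.74 CPM in the control group and 124 ± 18.4 CPM in the FGF19 group, and FGFR4 was at 10.4 ± 1.57 and 13.8 ± 1.29 CPM (SD, n = 3). FGFR3 had a log2 fold change of 0.64 ± 0.18 (SE, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0599), a call that DESeq2 made at an adjusted p of 0.0186 and limma-voom at 0.0497. KLB was low in both groups, at 0.598 ± 0.236 and 0.451 ± 0.115 CPM (SD, n = 3), and FGFR2 and KL had too few counts to be tested. Of the 4 receptor and co-receptor genes tested, 0 were called by edgeR over all genes, 1 by DESeq2 and 1 by limma-voom, 3 had an unadjusted p under 0.05 in edgeR, and 3 were higher when adjusted over the list alone. The list did not pass as a set (camera, Benjamini-Hochberg adjusted p = 0.159).

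Beyond FGF19, the FGF19 libraries held more of several surface, matrix and secreted-factor transcripts and less of others, among them a gel-forming mucin. FAP, a serine protease best known from activated fibroblasts, had 2 counts over the 3 control libraries and 1858 over the 3 FGF19 libraries, a ratio of 1003 with a 95% counting interval from 277 to 8285. The cytokine OSM (oncostatin M) rose from 0.803 ± 0.228 to 29.8 ± 5.11 CPM, and F3, the tissue factor that starts the extrinsic clotting pathway, rose from 7.64 ± 0.570 to 135 ± 18.7 CPM (SD, n = 3). MUC5AC, the main gel-forming mucin of airway goblet cells, fell from 2235 ± 412 to 444 ± 94.0 CPM (SD, n = 3), and the drug efflux pump gene ABCB1 fell from 9.83 ± 2.17 to 2.07 ± 0.329 CPM (SD, n = 3).

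In all, 2095 of 18729 genes tested were called, of which 1175 were higher and 920 lower with FGF19, and 1108 of them changed at least 2-fold, 742 upward and 366 downward. Protein-coding genes made up 1712 of the called genes, 954 of them higher and 758 lower. The groups' libraries did not overlap in any of the 2095 called genes, nor in 32.8% of all genes tested, where chance would give 10%. Of the called genes, 51 of the higher ones had 3 or fewer counts over the control libraries, and 2 of the lower ones had 3 or fewer over the FGF19 libraries. The count of called genes fell to 773 when a change beyond 0.5 on the log2 scale was tested for. It was 1067 without control replicate 1, 1577 without control replicate 2 and 2511 without control replicate 3. Without FGF19 replicate 1, 2 or 3 it was 1316, 1186 or 1120.

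Among called genes of at least 5 CPM, the 10 largest increases were FGF19, FAP, TNS4, ROS1, COL6A3, SLPI, OSM, RAMP1, F3 and THY1. TNS4, a focal adhesion protein gene, rose by 6.32 ± 0.27 on the log2 scale, and ROS1, a receptor tyrosine kinase gene, by 6.13 ± 0.39 (SE). COL6A3, a chain of collagen VI, rose from 0.293 ± 0.0185 to 19.1 ± 0.858 CPM, and SLPI, an inhibitor of leukocyte proteases, from 0.235 ± 0.0746 to 11.1 ± 0.793 CPM (SD, n = 3). RAMP1, a partner protein of the calcitonin receptor-like receptor, rose by 5.04 ± 0.35 on the log2 scale (SE), and the surface glycoprotein gene THY1 rose from 1.76 ± 0.133 to 28.1 ± 2.52 CPM (SD, n = 3). The 10 largest decreases were CLSTN2, CST4, BEND7, RGCC, NPTX1, ANKRD1, KCNMA1, MUC5AC, TOX and ABCB1. CLSTN2, a calsyntenin gene, fell from 12.4 ± 0.581 to 0.423 ± 0.275 CPM, and the salivary cystatin gene CST4 from 12.3 ± 1.53 to 1.13 ± 0.203 CPM (SD, n = 3). ANKRD1 fell from 48.0 ± 0.471 to 8.37 ± 0.619 CPM and KCNMA1, a calcium-activated potassium channel gene, from 17.7 ± 1.77 to 3.37 ± 0.116 CPM (SD, n = 3). BEND7, RGCC, NPTX1 and TOX had log2 fold changes of -3.04 ± 0.37, -2.63 ± 0.22, -2.55 ± 0.23 and -2.30 ± 0.17 (SE). CST4 has close relatives such as CST1, and reads that fit both make its level uncertain.

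**Figure D2:**
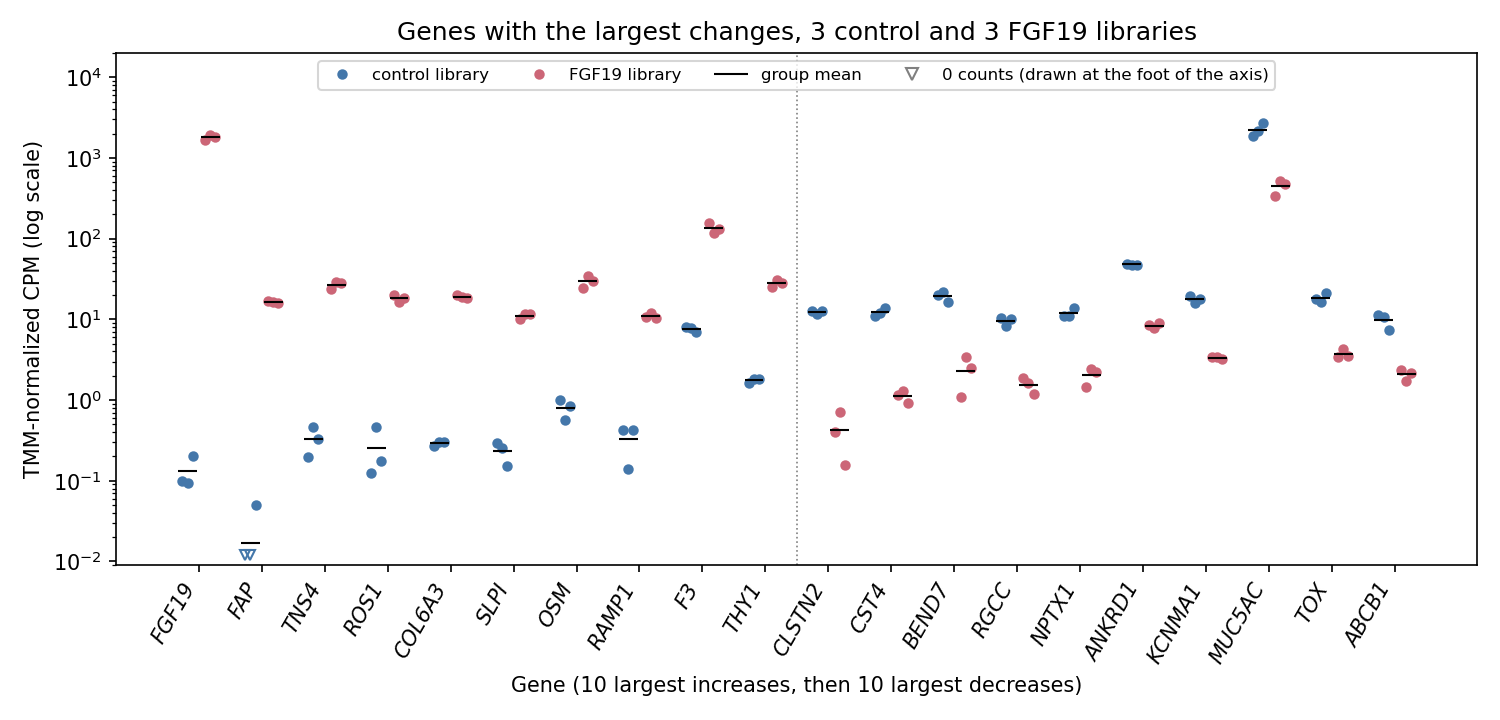
TMM-normalized CPM on a log axis for the 10 genes with the largest increases (left of the dotted line) and the 10 with the largest decreases (right). Each point is 1 library (blue for control, red for FGF19, 3 of each), black lines are group means, and open triangles at the foot of the axis are libraries with 0 counts. By the rule that chose these genes, the libraries of the 2 groups do not overlap for any of them.

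Among genes induced by low oxygen and genes of sugar breakdown, the members that were called all rose with FGF19. Of 16 hypoxia response genes, 9 rose and 0 fell, with 11 higher and 1 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 6.75e-06, and adjusted p = 0.133 with an estimated correlation). With library totals as the only scaling, 5 of them were called higher. CA9, a carbonic anhydrase of the cell surface, rose from 1.17 ± 0.127 to 9.92 ± 1.26 CPM, NDRG1 from 28.1 ± 3.86 to 90.5 ± 5.83 CPM, and the angiogenic factor VEGFA from 118 ± 22.4 to 366 ± 74.7 CPM (SD, n = 3). ANGPTL4, an inhibitor of lipoprotein lipase, rose by 2.12 ± 0.19 on the log2 scale (SE). Of 22 glycolysis and glucose transport genes, 4 rose and 0 fell, with 5 higher and 0 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00861, and adjusted p = 0.564 with an estimated correlation). They were PGK1, with a log2 fold change of 1.03 ± 0.08, the glucose transporter gene SLC2A3 with 1.42 ± 0.13, PFKFB3 with 0.57 ± 0.12 and ENO2 with 0.71 ± 0.17 (SE). The glucose transporter gene SLC2A1 was at 359 ± 88.6 CPM in the control group and 358 ± 29.3 CPM in the FGF19 group (SD, n = 3) and was not called.

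Several NF-kB targets and cytokines and some interferon-induced genes rose, while 2 of the NF-kB list fell. Of 19 NF-kB targets and cytokines, 9 rose and 2 fell, with 11 higher and 3 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000412, and adjusted p = 0.466 with an estimated correlation). CCL20, a chemokine for lymphocytes and dendritic cells, rose from 1.49 ± 0.242 to 16.4 ± 0.939 CPM, IL1A from 15.5 ± 3.88 to 63.2 ± 10.8 CPM and IL1B from 0.332 ± 0.227 to 7.33 ± 1.13 CPM (SD, n = 3). CSF3, the granulocyte colony-stimulating factor, had 0 counts in the control libraries and 221 in the FGF19 libraries, at least 26.5-fold higher against a floor of 3 counts per library. The chemokine gene CCL2 and TNFAIP3, an inhibitor of NF-kB signalling, fell, with log2 fold changes of -1.08 ± 0.13 and -0.59 ± 0.11 (SE). Of 23 interferon response genes, 5 rose and 0 fell, with 6 higher and 1 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00861, and adjusted p = 0.235 with an estimated correlation). They were OASL (1.82 ± 0.22), IFIT3 (1.14 ± 0.14), IFIT2 (0.96 ± 0.14), HERC5 (0.62 ± 0.12) and OAS2 (1.23 ± 0.31 on the log2 scale, SE), and the IFIT genes resemble each other enough to share reads. Of 13 antigen presentation genes, 0 rose and TAPBP fell, with 1 higher and 2 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.523).

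Several genes of matrix-degrading enzymes and their inhibitors rose, and epithelial, squamous and mesenchymal genes moved in both directions. Of 14 matrix protease and inhibitor genes, 8 rose and 1 fell, with 9 higher and 1 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000131, and adjusted p = 0.133 with an estimated correlation). The interstitial collagenase gene MMP1 rose by 4.93 ± 0.55 from a control level of 0.0333 ± 0.0289 CPM, the urokinase receptor gene PLAUR by 1.05 ± 0.13 and MMP14 by 1.00 ± 0.16 on the log2 scale (SE), while MMP7 fell from 8.80 ± 1.51 to 2.83 ± 0.509 CPM (SD, n = 3). Those that rose included the inhibitor genes TIMP1 and TIMP3. Of 15 mesenchymal genes, 4 rose and 3 fell, with 4 higher and 4 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.993). SNAI1, a repressor of epithelial genes, rose from 3.94 ± 0.673 to 14.7 ± 1.19 CPM, whereas the N-cadherin gene CDH2 fell from 186 ± 17.4 to 93.5 ± 3.25 CPM and the receptor kinase gene AXL from 498 ± 79.4 to 272 ± 17.2 CPM (SD, n = 3). Of 12 epithelial junction genes, 2 rose and 5 fell, and the same numbers held when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.531). The P-cadherin gene CDH3 rose by 3.28 ± 0.32, and KRT19, OCLN and EPCAM had log2 fold changes of -0.90 ± 0.12, -1.62 ± 0.24 and -0.91 ± 0.15 (SE).

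Of 13 squamous and basal keratinocyte genes, 4 rose and 3 fell, with 5 higher and 4 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.993). TP63, the transcription factor that marks basal and squamous cells, fell from 41.8 ± 1.60 to 14.7 ± 2.32 CPM, and the desmosome gene DSP from 41.5 ± 1.90 to 17.7 ± 1.47 CPM (SD, n = 3). SOX2 fell from 0.826 ± 0.129 to 0.137 ± 0.0972 CPM, while KRT17 rose from 0.223 ± 0.210 to 3.00 ± 0.528 CPM and the laminin chain gene LAMB3 from 612 ± 111 to 1302 ± 124 CPM (SD, n = 3). The basal keratin genes KRT5 and KRT14 had too few counts to be tested. Of 14 YAP/TAZ targets, 3 rose and 5 fell, with 5 higher and 5 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.993). Those that rose included F3 and CTGF, the latter by 0.78 ± 0.11 on the log2 scale (SE), and those that fell included ANKRD1 and AXL.

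Markers of other cell types also differed between the groups. Among 11 fibroblast and endothelial markers, 5 had enough counts to be tested, and 3 of these rose and 0 fell, with 4 higher when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000412, and adjusted p = 0.143 with an estimated correlation). They were THY1, whose values are given among the largest increases, PDGFRA and COL1A1. PDGFRA, a platelet-derived growth factor receptor gene, rose from 0.350 ± 0.240 to 4.21 ± 0.657 CPM, and COL1A1, a chain of collagen I, from 295 ± 34.2 to 548 ± 52.4 CPM (SD, n = 3). COL1A2, the partner chain of COL1A1 in collagen I, had 2 counts over the control libraries and 4 over the FGF19 libraries. Among 10 lung alveolar and airway markers, 3 were tested, and MUC5B rose and MUC5AC fell, both also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.595). MUC5B was at 0.139 ± 0.117 CPM in the control group and 0.965 ± 0.370 CPM in the FGF19 group (SD, n = 3), and it is a neighbour and relative of MUC5AC, so shared reads leave its level uncertain. Among 11 kidney, liver and neuroendocrine markers, 5 were tested, and the fetal albumin-like gene AFP and the transcription factor gene PAX8 rose, by 1.88 ± 0.21 and 1.17 ± 0.27 on the log2 scale (SE), both also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.372). Of 8 leukocyte markers, CD14 and CD68 had enough counts to be tested and 0 were called by edgeR, over all genes or adjusted over the list alone, 0 by DESeq2 and 0 by limma-voom, while 1 had an unadjusted p under 0.05 in edgeR. CD14 had a log2 fold change of 2.16 ± 0.80 (SE, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.135).

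Feedback genes of the MAPK cascade, which lies downstream of FGF receptors, moved in both directions. Of 19 MAPK feedback and early response genes, 4 rose and 1 fell, with 6 higher and 2 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.141). DUSP6, an ERK phosphatase, rose from 15.1 ± 3.92 to 42.6 ± 6.53 CPM, and FOS from 1.47 ± 0.362 to 3.52 ± 0.194 CPM (SD, n = 3). IER3 and SPRY4 rose by 0.76 ± 0.13 and 0.77 ± 0.15 on the log2 scale, whereas SPRY1, also a feedback inhibitor, had a log2 fold change of -1.09 ± 0.20 (SE). Of 12 FOXO and nutrient withdrawal genes, 4 rose and 3 fell, the same numbers as when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.371). The insulin receptor gene INSR rose by 1.29 ± 0.13, TXNIP by 2.04 ± 0.22 and TRIB1 by 0.77 ± 0.09 on the log2 scale (SE), while PDK4 fell from 1.67 ± 0.135 to 0.484 ± 0.125 CPM (SD, n = 3).

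Single members of the stress and survival lists changed, and none of these 6 lists passed camera as a set in the fit of all 6 libraries. Fry called the NRF2 list and the lysosome list higher (fry, adjusted p = 0.00838 for each) and did not call the others. Of 17 NRF2 targets, 4 rose and 2 fell, with 5 higher and 3 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.289). Heme oxygenase (HMOX1) rose by 2.12 ± 0.16 on the log2 scale (SE), and the aldo-keto reductase genes AKR1C2 and AKR1C1 rose from 31.9 ± 1.16 to 237 ± 5.69 CPM and from 495 ± 16.7 to 1201 ± 67.5 CPM (SD, n = 3). AKR1C1, AKR1C2 and AKR1C3 are closely related genes, so the split of reads between them is uncertain. GCLC, which makes the precursor of glutathione, fell from 412 ± 30.6 to 205 ± 9.69 CPM (SD, n = 3). Of 17 autophagy and lysosome genes, 3 rose and 0 fell, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0718). These were the cathepsin genes CTSB (1.41 ± 0.10) and CTSL (1.49 ± 0.12) and the cholesterol exporter gene NPC1 (1.32 ± 0.09 on the log2 scale, SE). Of 16 p53 targets, the cell cycle inhibitor gene CDKN1A rose from 65.5 ± 11.1 to 131 ± 10.1 CPM (SD, n = 3) and 0 fell, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.993). Of 12 BCL2 family genes, the survival genes BCL2L1 and MCL1 rose, by 0.74 ± 0.14 and 0.50 ± 0.10 on the log2 scale (SE), also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.564). Of 19 ATF4 and amino acid response genes, VLDLR rose and PHGDH, which opens serine synthesis, fell, by 0.52 ± 0.10 and with a log2 fold change of -0.86 ± 0.17 (SE), also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.993). Of 17 ER chaperone genes, MANF rose by 0.53 ± 0.10 on the log2 scale (SE) and 0 fell, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.141).

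Cholesterol synthesis and mitosis genes were lower as sets, by small amounts. Of 20 cholesterol synthesis and uptake genes, 0 rose and 2 fell, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0294, and adjusted p = 0.235 with an estimated correlation). These were INSIG1, a brake on sterol synthesis, with a log2 fold change of -0.64 ± 0.12, and ACAT2 with -0.66 ± 0.13 (SE). Of 10 fatty acid synthesis genes, 0 rose and the desaturase gene SCD fell from 150 ± 3.73 to 99.3 ± 6.35 CPM (SD, n = 3), with 2 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.141). Of 18 G2/M and mitosis genes, 0 rose and the mitotic kinesin gene KIF20A fell from 87.5 ± 4.20 to 65.7 ± 3.09 CPM (SD, n = 3), with 0 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0131, and adjusted p = 0.235 with an estimated correlation). Of 20 G1/S and DNA replication genes, CCNE1 rose by 0.41 ± 0.10 on the log2 scale and TYMS fell with a log2 fold change of -0.52 ± 0.10 (SE), with 2 higher and 1 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.827). CCNE1 lost the call in 11 of 17 alternatives, among them library totals as the only scaling and each of the 6 left-out libraries, and KIF20A lost it in 8, among them 5 left-out libraries.

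Mitochondrially encoded mRNAs made up 17.7% ± 2.29 of counts in the control group and 20.3% ± 0.803 in the FGF19 group (SD, n = 3, two-sided exact permutation p = 0.1, the smallest p that 3 against 3 libraries allow). The mitochondrial ribosomal RNAs took 2.23% ± 0.131 and 1.85% ± 0.220 of counts (SD, n = 3, two-sided exact permutation p = 0.1). Of 13 mitochondrially encoded mRNAs, 0 were called by edgeR, over all genes or adjusted over the list alone, 0 by DESeq2 and 0 by limma-voom, while 3 had an unadjusted p under 0.05 in edgeR. As a set they were called higher only with the preset correlation (camera, Benjamini-Hochberg adjusted p = 0.0208, and adjusted p = 0.678 with an estimated correlation of 0.715). Fry did not call the set (adjusted p = 0.248). The camera call was lost without control replicate 1 (camera, adjusted p = 0.251) and without FGF19 replicate 2 (0.0864). MT-CO3 had the smallest p among them, with a log2 fold change of 0.40 ± 0.12 (SE, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0758). Of 18 nuclear genes for subunits of oxidative phosphorylation, 0 were called by edgeR, over all genes or adjusted over the list alone, 1 by DESeq2, 1 by edgeR with library totals as the only scaling and 0 by limma-voom, while 2 had an unadjusted p under 0.05 in edgeR (camera, Benjamini-Hochberg adjusted p = 0.292). ATP5G1 had the smallest p, with a log2 fold change of -0.52 ± 0.15 (SE, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0624). Of 18 ribosomal protein genes, 0 rose and RPS6 fell, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0257, and adjusted p = 0.564 with an estimated correlation). RPS6 (chromosome 9 from 19375715 to 19380254, GRCh38) fell from 693 ± 16.7 to 300.2 ± 12.6 CPM (SD, n = 3).

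**Figure D3:**
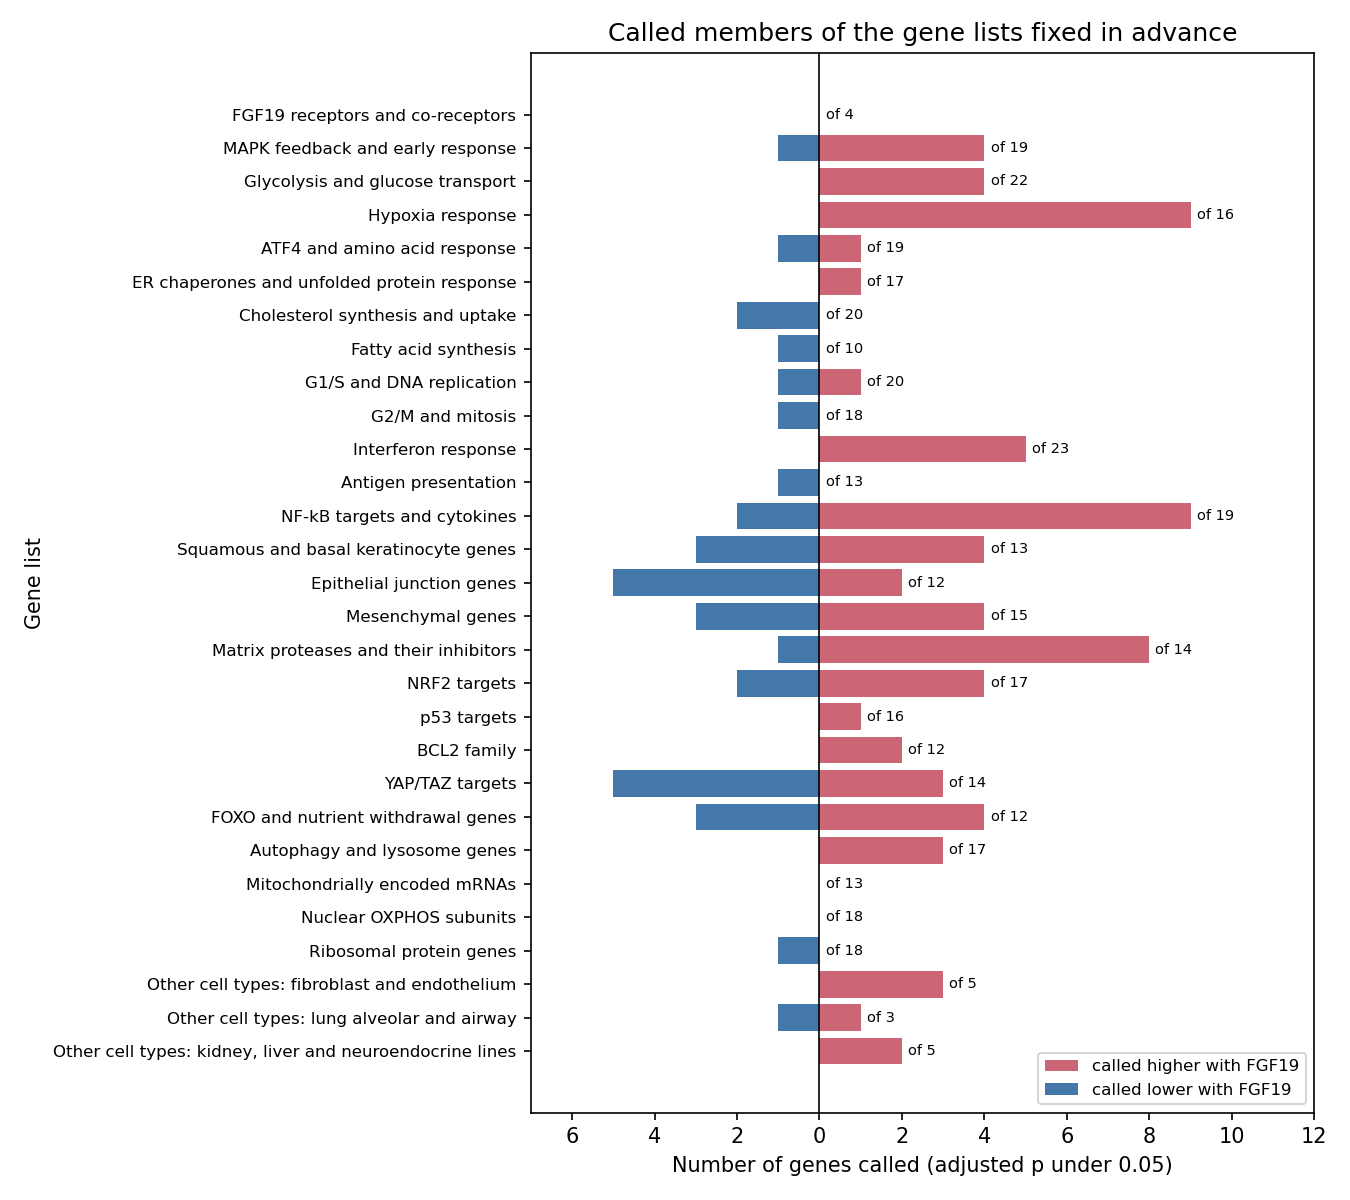
Number of called genes in each gene list with at least 3 tested members, with genes called higher with FGF19 to the right (red) and lower to the left (blue). The number beside each bar is how many members were tested. The hypoxia list has 9 of 16 members higher and the NF-kB list 9 of 19.

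With the preset correlation, 10 of 29 lists were called, 7 higher and 3 lower, and with a correlation estimated from these libraries camera called 0, with 6 at an unadjusted p under 0.05, while fry, which asks whether a list's genes move one way on balance, called 13. The estimated correlation was below the preset 0.01 for hypoxia (-0.039), matrix protease (-0.023), cholesterol (-0.037) and fibroblast and endothelial genes (-0.095). For the other called lists it was above 0.01, from 0.011 for interferon genes to 0.715 for mitochondrial mRNAs. A lost call is thus not by itself a sign that a list's genes vary together. PHGDH, TXNIP, ACAT2 and RPS6 lie in stretches of chromosomes 1, 6 and 9 where neighbouring genes shifted together. In the stretch with PHGDH and TXNIP the median log2 fold change of the 121 genes of at least 5 CPM was -0.37, in that with ACAT2 it was -0.49 over 71 genes, and in that with RPS6 it was -0.24 over 61 genes. PHGDH, ACAT2 and RPS6 fell like their stretches. TXNIP rose, but it starts at 145992435, near the upper end of its stretch, while the strongest window there ended at 119647773. Of the windows beyond the largest shuffled deviation, TXNIP lay only in the weakest of that stretch. The median of the stretch therefore does not show whether the genes next to TXNIP were lowered. With the 699 genes of at least 5 CPM in such stretches, which were found after seeing the data, left out and genes under 5 CPM kept, 1906 genes were called, 1099 higher and 807 lower. Of the 75 called genes among the 86 that the naming rule gave besides FGF19, 21 lost the call in at least 1 of 17 alternatives, and after CCNE1 and KIF20A these were led by PAX8 in 7 and ACAT2, MCL1, PFKFB3 and VLDLR in 6 each.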

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

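Apart from the count without genes of the shifted stretches, the alternatives were chosen before the data were examined. FGF19 itself kept its direction and its call in each alternative run, with log2 fold changes from 13.52 to 14.15, and 10.04 on the log2(TPM + 1) scale, which understates changes from a level near 0. The count of called genes, 2095, was 2102, 2111 and 2107 with RLE, upper-quartile and total-only scaling, 2095 with FGF19 left out of the totals, 2784 with DESeq2, 2119 with limma-voom, 1769 with limma on log2(TPM + 1), 1618 with no low-count filter, 1736 with the stricter filter and 1906 without the 699 genes of at least 5 CPM in the shifted stretches, where genes under 5 CPM were kept. It was 773 with glmTreat, which tests for a change beyond 0.5 on the log2 scale. Leaving out 1 library gave 1067 to 2511 called genes, with 1067 without control replicate 1, 1577 without control replicate 2, 2511 without control replicate 3, and 1316, 1186 and 1120 without FGF19 replicates 1, 2 and 3. Such fits have fewer samples. The median log2 fold change of all genes was -0.013 with TMM, -0.0096 with RLE, 0.0013 with upper-quartile factors and -0.054 with library totals.

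No pairing by replicate number was seen. Same-numbered libraries deviated from their group means with correlations across genes of 0.04, -0.18 and -0.04, against -0.16 to 0.20 for differently numbered libraries of the 2 groups. With 3 libraries per group these correlations cannot exclude a pairing. With the replicate block, a fit with fewer residual degrees of freedom, 1127 genes and 9 lists were called.

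Of the lists, 10 were called in the main test, 0 with an estimated correlation (6 at an unadjusted p under 0.05), 13 with fry, 10 with RLE and 8 to 11 with 1 library left out. By camera, the mitochondrial list was lost without control replicate 1 (adjusted p = 0.251) and FGF19 replicate 2 (0.0864), the ribosomal list without control replicates 1 (0.0642) and 3 (0.176), without FGF19 replicate 1 (0.139) and with the block (0.0511), the glycolysis list without control replicate 2 (0.0627), and the cholesterol list without FGF19 replicate 2 (0.0511). Lists that were gained, all upward, were MAPK feedback without control replicate 3 (camera, adjusted p = 0.0306), lysosome genes without control replicate 3 (0.0414) and FGF19 replicate 1 (0.0408), and ER chaperones without control replicate 1 (0.0348). Fry, against the main test, left out the mitochondrial and ribosomal lists and added fatty acid synthesis, NRF2, FOXO, lysosome and kidney, liver and neuroendocrine genes. Among 86 named genes besides FGF19, 75 were called, of which 54 kept the call in each alternative that gave a value and 21 lost it in at least 1 of 17. CCNE1 lost it in 11, KIF20A in 8, PAX8 in 7, and ACAT2, MCL1, PFKFB3 and VLDLR in 6 each, followed by INSIG1, MANF, TAPBP, TYMS, PHGDH, BCL2L1 and MUC5B. AKR1C1, AXL, CTGF, IER3, OCLN, SCD and TRIB1 lost it in 1, glmTreat or the TPM scale. Without control replicate 3, FGFR3, MT-CO3, MT-CO1 and CD14 were called, with adjusted p-values of 0.0311, 0.0327, 0.0327 and 0.0196 (edgeR). ATP5G1 was called with library totals (edgeR, adjusted p = 0.0329), DESeq2 (0.0241) and limma on log2(TPM + 1) (0.0213). MT-CO2, not called, reversed without control replicate 1, to -0.036, in a range from -0.036 to 0.26 over the left-out libraries. The cause was not tested for any of these changes. Depth limited genes with few counts, since 51 of the genes called higher had 3 or fewer control counts and their fold rests on them.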

Other observations

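The gene families, the single genes named beside them or near RPS6, and the tests of a general decline of ribosomal protein mRNAs and of fibroblast admixture were chosen only after the results were seen. The other tests on RPS6, FAP and the chromosome stretches were fixed after these patterns were noticed but before the values that decide them were computed.

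Among families of genes that share a symbol, collagens, clade B serpins and ADAMTS proteases held more genes that rose with FGF19 than protein-coding genes at large. Of 29 collagen genes tested, 11 rose and 0 fell (Fisher's exact test, two-sided, against the other protein-coding genes, 6.84% of all of which were called higher, Benjamini-Hochberg adjusted p = 0.000763 over 480 tests of 240 families). They included COL13A1, from 1.43 to 7.33 CPM, COL6A2 with a log2 fold change of 0.80 ± 0.14 and COL5A1 with 0.52 ± 0.11 (SE). Of 10 clade B serpin genes, 6 rose and 0 fell (Fisher's exact test, adjusted p = 0.0033). SERPINB2, SERPINB3, SERPINB4 and SERPINB7, which rose, lie together on chromosome 18 from 63637259 to 63903890. SERPINB1 and SERPINB9, which also rose, lie together on chromosome 6 from 2832332 to 2903280. The test counted these neighbours as independent genes. SERPINB2, an inhibitor of plasminogen activators, rose from 153 ± 13.4 to 800 ± 103 CPM (SD, n = 3), and SERPINB3, at 0 counts in the control libraries, reached 3.62 ± 0.285 CPM but shares reads with its near copy SERPINB4. SERPINB4 also had 0 counts in the control libraries and reached 0.651 ± 0.289 CPM in the FGF19 group (SD, n = 3). Of 13 ADAMTS protease genes, 6 rose and 1 fell (Fisher's exact test, adjusted p = 0.0137), and of 13 ADAM genes, 5 fell and 1 rose (adjusted p = 0.04). Among the ADAMTS genes that rose, ADAMTS5, ADAMTS17 and ADAMTS18 stayed under 1 CPM in both groups. Their means went from 0.0658 to 0.299, from 0.0407 to 0.328 and from 0.0329 to 0.812 CPM. ADAMTS1, ADAMTS6 and ADAMTS14, which also rose, were above 1 CPM in both groups. The test counted genes whatever their level. Of 43 genes with symbols of the interleukin series, receptors included, 12 rose and 3 fell (Fisher's exact test, adjusted p = 0.0033). Under RLE, upper-quartile and total-only scaling the counts higher stayed at 11 for collagens and 6 for clade B serpins, and were 5 or 6 for ADAMTS genes and 12 or 13 for the interleukin series, with 5 ADAM genes lower in each.

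Single genes outside the lists also rose. The complement genes C1S and C3 rose from 12.4 ± 3.24 to 149 ± 28.3 and from 135 ± 21.9 to 607 ± 67.6 CPM (SD, n = 3), and C1R rose by 3.04 ± 0.22 on the log2 scale (SE). OSMR, the receptor gene for OSM, rose by 1.36 ± 0.10 and SOCS3, a feedback inhibitor of cytokine receptors, by 1.80 ± 0.19 on the log2 scale (SE). PTGS2, an inducible prostaglandin synthase gene, rose from 8.44 ± 0.254 to 73.2 ± 5.11 CPM, STC1 from 13.2 ± 0.350 to 144 ± 4.62 CPM, and IGFBP4, which binds insulin-like growth factors, from 74.2 ± 16.3 to 611 ± 96.8 CPM (SD, n = 3). EPAS1, which encodes the oxygen-regulated factor HIF-2alpha, rose by 3.94 ± 0.23 on the log2 scale (SE). All of these were called in the same direction by edgeR under each of the 4 scalings.

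Of the 10 splits of the 6 libraries into 3 and 3, 1, the real split, gave as many called genes (2095), and the highest of the others gave 2. With 10 splits a share under 0.05 cannot be reached.

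RPS6 fell from 693 ± 16.7 to 300.2 ± 12.6 CPM (SD, n = 3), while the other 78 RPL and RPS genes tested had 0 called by edgeR, or 2 lower with total-only scaling. Their median log2 fold change was -0.18, with quartiles from -0.24 to -0.09, against -1.21 ± 0.09 (SE) for RPS6, which leaves a small general decline of ribosomal protein mRNAs open but argues against it as the source of a fall as large as that of RPS6. Reads moved to the 7 RPS6 pseudogenes of the table do not account for it either, since these changed by -0.0515% of the CPM that RPS6 lost. Reads that went to other copies, or were left out because they fit several genes, would not show in this test. The 40 genes around RPS6 had a median of -0.47, below the lowest of 1000 random sets (-0.24), with 26 of the 40 below 0, 19 called lower and 3 higher, and of the 10 nearest, 9 fell, among them MTAP, FOCAD and DENND4C. A lower copy number or activity of part of that stretch of chromosome 9 in the FGF19 cells is a candidate explanation, as a hypothesis, and DNA was not analysed here.

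Neighbouring genes shifted together in several stretches, with 41 of 1068 windows beyond the largest shuffled deviation of 0.26, 24 of them lower and 17 higher. The strongest on 4 chromosomes were chromosome 1 from 111139627 to 119647773 (median -0.62, with 40 of 41 genes on the window's side of the median of all genes of at least 5 CPM), chromosome 6 from 149658153 to 165986603 (-0.56, 38 of 41), chromosome 9 from 6011043 to 33473930 (-0.62, 27 of 41, with an upper quartile of 0.22) and X from 149476990 to 153971807 (0.53, 39 of 41), so the window on chromosome 9 did not shift as a whole. Genes of 1 to 5 CPM, which had no part in finding the windows, had medians of -0.34, -0.36, -0.64 and 0.11, so 3 of the 4 windows reached the 0.3 set for a difference in DNA copy number, which may explain these and did not reach that bound on X. For a few co-regulated genes per stretch, under 60% of such genes on the window's side was set to favour that explanation and at least 75% to count against it. The share was 74.6% of 59 genes, just under 75%, so the test did not decide. Its 95% Clopper-Pearson interval, 61.6% to 85.0%, treats neighbouring genes as independent and may be too narrow. Whether a difference in DNA copy number arose with FGF19 or between separately kept cultures was not tested.

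FAP, THY1, COL6A3 and PDGFRA, genes common in fibroblasts, rose in the FGF19 libraries. Mixed-in fibroblasts could bring such transcripts, but all 4 of COL1A2, COL3A1, DCN and LUM, abundant in those cells, had means under 10% of that of FAP in the FGF19 libraries, at 0.206%, 0.160%, 0.160% and 2.14% of its 16.3 ± 0.444 CPM (SD, n = 3), which argues against fibroblasts as the source. The neighbours, 40 per gene, argue against a shift of the broad stretch around each gene. Their median log2 fold change was under 0.15 for 4 of the 4 genes (-0.13, -0.098, -0.0013 and -0.14, in the order FAP, THY1, COL6A3 and PDGFRA). Such medians cannot show a change of only a few adjacent genes. RAMP1 (chromosome 2 from 237858893 to 237912114), which also rose, lies close to COL6A3 (237324003 to 237414375). The 40 neighbours of COL6A3 held 6 genes called higher and 4 called lower. Another cell type without these collagens, a change of a few adjacent genes, and a response of the cells themselves to FGF19 stay open and were not tested.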
